A study of Mus musculus with 2 samples.

How the data were processed

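The deposited files hold counts: raw UMI counts per gene and barcode that the authors made with Cell Ranger, with no normalisation, for 2 libraries labelled WT and KO. Each library came from 10 TA muscles of 5 male mice, digested for 1 h at 37 °C, and about 200000 viable cells were sorted per sample. Libraries were made with 10x Genomics GEM-X 3' chemistry version 4, with a target of 20000 cells and about 40000 reads per cell per the labels. Per the submitters' processing notes the tool was Cell Ranger 9.0.0 with build mm10, whereas the file headers name 8.0.0 for the library labelled WT and 9.0.0 for the library labelled KO. Both libraries list the same 33696 genes, of which 1735 identifiers are not in GENCODE M21, so no coordinates are given. The barcodes as deposited have at least 500 UMIs each. The abbreviation ND in the labels is not spelled out and was given no meaning.

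Barcodes were kept with at least 500 detected genes, at most 10% mitochondrial UMIs and no doublet call. In the library labelled WT 1038 of 11360 barcodes had under 500 genes, 84 had over 10% mitochondrial UMIs and 91 were called doublets (0.801%, against 4.54% expected from 0.4% per 1000 barcodes). In the library labelled KO these counts were 922, 123 and 715 of 19531 (3.66%, against 7.81% expected). Doublets were called by the Scrublet method per library with 30 components. The calls fell short of the expected rates in both libraries, so doublets remain among the kept barcodes. In all 10184 barcodes (89.6%) and 17854 barcodes (91.4%) were kept.

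Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen per library and combined, and 30 principal components with 20 neighbours fed a shared nearest-neighbour graph for Leiden clustering at resolution 1. No batch integration was used, because library and genotype are the same split and the labels give both libraries the same batch. Classes were named from marker lists fixed before the data were examined and are called X-like. FAP-like cells were 4 clusters, with leading genes that include Apod in 1 of them and Grm8 in another, and they were clustered again at resolution 0.5. Clusters that met no naming rule stayed without a class.

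Within a class the counts were summed per library and scaled to CPM by the class total, and log2 ratios of the library labelled KO over the library labelled WT used a pseudocount of 1 CPM. Genes were compared with at least 20 CPM in 1 library and at least 100 UMIs over both, in the 10 classes with at least 100 cells per library. Shares have exact Clopper-Pearson intervals, levels exact Poisson intervals and ratios exact conditional binomial intervals, all at 95% and for counting error alone. The ratio intervals were computed from the counts without the pseudocount, so at low levels they are not centred on the printed ratio. A count of 0 was given the limit of 3 counts. With 1 library per group no test between genotypes was run, since cells of 1 library are not replicates. Gene lists, 23 of pathways and 4 of FAP states, were fixed before the data were examined. Each list's median over members at 5 CPM or more was placed among 10000 random lists matched on mean expression in 20 bins, and members at least 1.5-fold apart were counted. Of the list genes, 4 were not used here.

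Named genes followed a rule fixed in advance. For FAP-like cells it took IGF axis genes at 20 CPM or more, the 12 largest and 12 smallest log2 ratios among genes with at least 50 CPM in 1 library and 200 UMIs, and the 4 members of each list furthest from 0. It left out mitochondrial, ribosomal protein and haemoglobin genes, predicted genes, and genes over 5 times higher in the other cells of the library. For other classes it took the 5 largest and 5 smallest and 4 per list. Gm8797 is named because it was the 1 gene set apart in every class, and Hbb-bs, Dcn, Pecam1, Xist and Ddx3y are named as markers. Some genes that the rule takes are not reported. The equal mix of sub-clusters averages those with at least 30 cells per library, a floor set after the data were seen.

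The procedure was tested on simulated data made from FAP-like cells, with 200 genes altered among 6816 past the floors. It called 100% of the genes altered 3-fold in either direction, 0% of those altered 1.5-fold, and 0 of 6619 unaltered genes. The interval held the true ratio for 95% of altered genes, 5.33% of 300 unaltered lists of 17 genes lay outside the central 95%, and 100% of lists shifted by 0.3 lay above it. The simulated counts came from a pooled profile with Poisson error alone. Differences between cells, states or libraries were absent, so these rates are not false-call rates for the real comparison. Alternatives to the filters, doublet removal, clustering, scaling, weighting, depth, FAP-like gate, floors and pseudocount were tried, 16 planned and 5 added after the data were seen. The strict filter took at least 1000 genes and at most 5% mitochondrial UMIs, the loose filter at least 200 genes and at most 20%, run for cell counts and shares, and the finer clustering used resolution 2. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, the last for TMM factors with no test. Raw reads were not used here.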

Results

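Single-cell RNA counts were measured in cells freshly isolated from the tibialis anterior (TA) muscle of male mice, in 1 library labelled WT and 1 library labelled KO. Each library pooled 10 TA muscles from 5 mice of its strain. Fibro-adipogenic progenitors (FAPs) are the resident mesenchymal cells of skeletal muscle, and the series concerns insulin-like growth factor I made by these cells. Although the labels call the cells FAPs, the suspension was sorted only for viability by propidium iodide after red cell lysis, and it held many cell types. The library labelled WT had 11360 barcodes with 38014703 UMIs and a median of 2688.5 UMIs per barcode. The library labelled KO had 19531 barcodes with 101570863 UMIs and a median of 4010 UMIs per barcode. The submitters state about 15000 retained cells per sample. After filtering, 10184 barcodes remained in the library labelled WT and 17854 in the library labelled KO, with medians of 2939 and 4208.5 UMIs. Ddx3y, a gene of the Y chromosome, was at 174 and 164 CPM (UMIs relative to the total of the cells summed), while Xist, the transcript of the inactive X chromosome, was at 0.14 and 0.16 CPM. With 1 library per genotype, no difference below has a replicate check, and every interval covers counting error alone.

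The first comparison asks whether Igf1, the gene named by the series title, was lower in FAP-like cells of the library labelled KO. Igf1 (ENSMUSG00000020053), which encodes the secreted growth factor IGF-I, was not lower there. Its level in FAP-like cells was 369 CPM in the library labelled WT (3256 UMIs; exact Poisson 95% interval 356 to 382) and 394 CPM in the library labelled KO (4683 UMIs; 383 to 406). The log2 ratio was 0.10, with an exact conditional interval of 0.03 to 0.16, and it was 0.51 with each library clustered alone. In that setting FAP-like cells were 12.5% of the library labelled WT, against 15.1% in the main setting. Their share of the library labelled KO was 5.965 against 5.96%. The 0.51 thus compares a different set of FAP-like cells of the library labelled WT. In tenocyte-like cells, the fibroblasts of tendon, Igf1 was at 239 CPM in the library labelled WT and 77.6 CPM in the library labelled KO, a log2 ratio of -1.61 (-1.80 to -1.45). Macrophage-like cells held 60.6 and 14.6 CPM, a log2 ratio of -1.98 (-2.52 to -1.60), but the proportions of their clusters differed between the libraries, and 1 cell held 30.5% of the Igf1 UMIs of the library labelled KO.

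Igf1 was also lower in endothelial-like cells of the library labelled KO, at 13.7 and 4.55 CPM, and near its floor in mural-like cells, at 3.59 and 1.27 CPM. At these low levels free RNA is not separated from expression, and its Igf1 content may differ between the libraries. Myogenic-like cells held 21.5 and 22.2 CPM, and perineurial-like cells, which sheathe nerve bundles, held 72.0 and 137 CPM. At least 1 Igf1 UMI was found in 50.8% of FAP-like cells of the library labelled WT, with a median of 5465 UMIs per cell, and in 60.1% of those of the library labelled KO, with a median of 10524 UMIs. With every cell thinned to 2000 UMIs the shares were 33.3% (30.8 to 35.8%) and 33.7% (30.8 to 36.7%), with 140 and 50 shallower cells left out. T-cell-like cells had no Igf1 UMI in 153 cells (median 3527 UMIs) and in 160 cells (median 7728.5 UMIs), which allows shares of cells with a UMI of up to 1.96% and 1.88%. The labels do not state which part of the gene is removed or in which cells, so 3' tags may lie outside the removed part and then check nothing about the genotype.

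**Figure D1:**
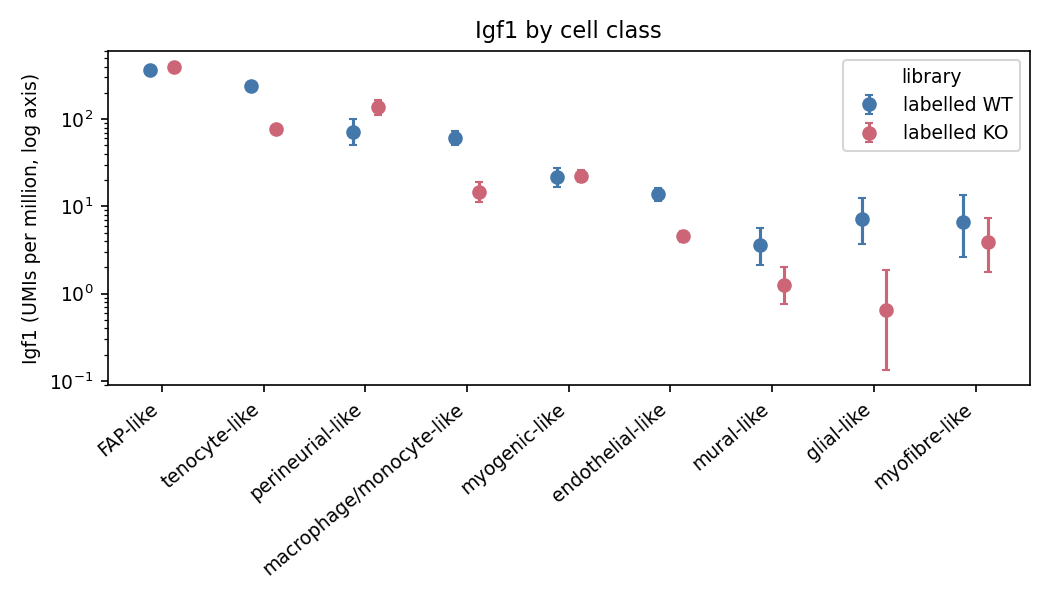
Igf1 level in CPM on a log axis by cell class for the libraries labelled WT and KO, as points with exact Poisson 95% intervals. FAP-like cells lie at 369 and 394 CPM, while tenocyte-like cells lie at 239 and 77.6 CPM.

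Cell class shares were compared next. FAP-like cells made up 15.1% of the barcodes of the library labelled WT (1542 cells; Clopper-Pearson interval 14.5 to 15.9%) and 5.96% of those of the library labelled KO (1064 cells; 5.62 to 6.32%). Tenocyte-like cells were 7.55 and 3.23%, perineurial-like cells 1.60 and 0.784%, macrophage-like cells 3.46 and 1.85%, and B-cell-like cells 1.06 and 0.442%. Endothelial-like cells were a larger share of the library labelled KO, at 33.2 and 39.8%, as were neutrophil-like cells, at 0.53 and 1.23%.

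The library labelled KO also held a cluster of 2863 barcodes, 16.0% of its total, with no barcode from the library labelled WT, where a count of 0 allows up to 0.0295%. These barcodes had a median of 1348 UMIs, against 5007 in the other cells of that library, and carried Dcn, a FAP gene, at 2556 CPM together with Pecam1, an endothelial gene, at 701 CPM. The other cells of that library, summed over classes, had similar levels, 2876.5 and 746 CPM. The file headers name Cell Ranger 8.0.0 for the library labelled WT and 9.0.0 for the library labelled KO. Without that cluster FAP-like cells were 7.10% of the library labelled KO (6.69 to 7.52%), or 0.469 times the share in the library labelled WT. On the same footing endothelial-like cells were 47.4%, 1.43 times the share in the library labelled WT. Mural-like cells, the pericytes and smooth muscle of vessels, were 16.1 and 15.3%, glial-like cells 5.19 and 5.46%, and myofibre-like cells 4.69 and 4.96%. Myogenic-like cells, which include satellite cells, were 8.66 and 7.08%. Over all kept barcodes, myofibre-like cells were 1.80 and 12.5% with the strict filter, 0.565 and 0.717% with doublets kept and 0.245 and 4.16% with each library clustered alone, and glial-like cells were 0.599 and 4.59% in the last of these. Endothelial-like cells were 31.5 and 54.3% with the loose filter, and erythroid-like cells 0.079 and 16.2% at the finer clustering. In the library labelled KO, barcodes without a class were 18.1% in the main setting, 2.33% with the loose filter and 6.03% at the finer clustering. With the strict filter every barcode had a class. The low-UMI barcodes may have taken class names in those settings, so their shares do not compare with the main ones.

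**Figure D2:**
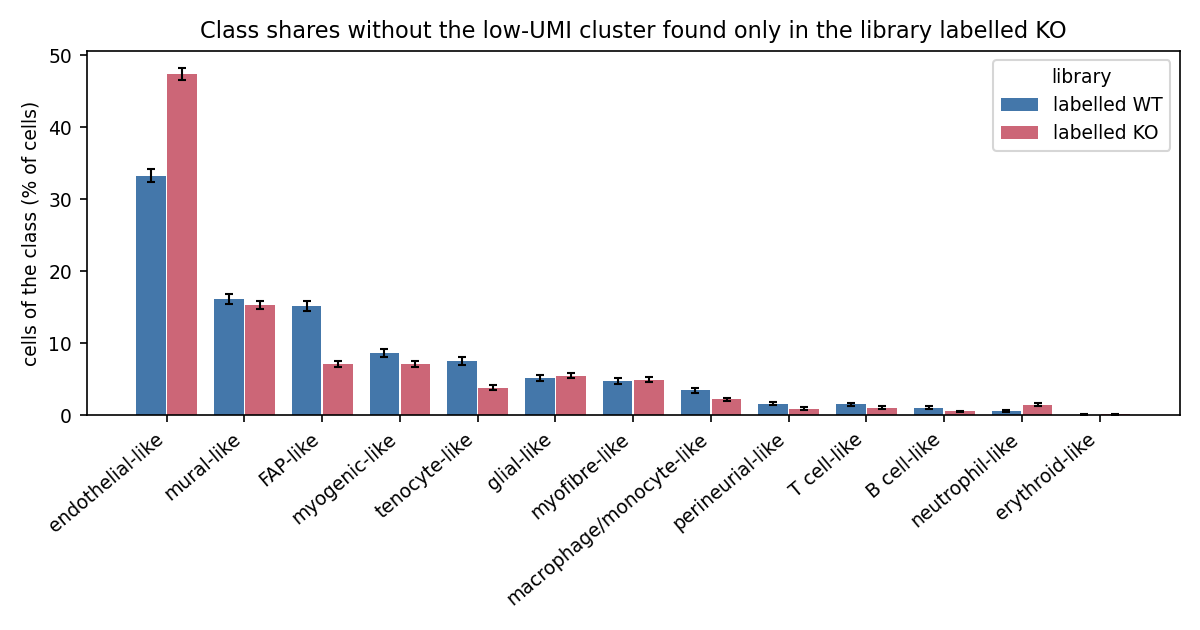
Bars give each cell class as a percent of the kept barcodes of the libraries labelled WT and KO, without the low-UMI cluster and with exact Clopper-Pearson 95% intervals; barcodes with no class are counted in the total and not drawn. FAP-like cells lie at 15.1 and 7.10%, tenocyte-like cells at 7.55 and 3.84%, and endothelial-like cells at 33.2 and 47.4%.

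Gene levels within FAP-like cells were then compared between the libraries. The genes furthest higher in the library labelled KO included F2rl1 (ENSMUSG00000021678), which encodes the protease-activated receptor PAR2, at 3.17 CPM in the library labelled WT and 70.8 CPM in the library labelled KO, a log2 ratio of 4.10 (3.94 to 5.08). Ccl2 (ENSMUSG00000035385), a chemokine that recruits monocytes, was at 80.2 and 718 CPM, a log2 ratio of 3.15 (3.05 to 3.28). Thbs1 (ENSMUSG00000040152), a matricellular protein that activates latent TGF-beta, was at 434 and 3253 CPM, a log2 ratio of 2.90 (2.86 to 2.95). Pdgfra (ENSMUSG00000029231), the growth factor receptor used to mark FAPs, was lower in the library labelled KO, at 750 and 396 CPM, a log2 ratio of -0.92 (-0.97 to -0.87). At an equal mix of FAP-like sub-clusters, a summary chosen after the data were seen, F2rl1 had a log2 ratio of 2.59, Ccl2 1.82, Thbs1 1.95 and Pdgfra -0.88. That mix covers 8 sub-clusters with 1475 and 727 cells and leaves out the sub-cluster led by F2rl1 and Thbs1, which held 14 and 266 cells.

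Of 7162 genes past the level floors in FAP-like cells, 283 were at least 2-fold higher and 173 at least 2-fold lower in the library labelled KO. Further genes among the 12 furthest higher were Fosl1, an AP-1 transcription factor on the dissociation stress list, with a log2 ratio of 2.85, the TWEAK receptor gene Tnfrsf12a with 2.73, and Ccn2, a matricellular growth factor gene, with 2.17. Rrs1, Gar1 and Heatr1, which act in ribosome biogenesis, had log2 ratios of 2.18, 1.93 and 1.87. The mitochondrial nucleotide carrier gene Slc25a5 had 1.94 and the CTP synthase gene Ctps 1.91. At the other end, Ppp2r2b, a phosphatase subunit gene, had a log2 ratio of -2.02, the interferon-inducible gene Ifi27l2a -1.95, G0s2, an inhibitor of fat breakdown, -1.64, and Col4a4, a basement membrane collagen gene, -1.42. The 8 others among the 12 furthest lower were Rtl4, Hmgn3, Rab30, Trhde, Limch1, Rgs6, Inmt and Adam33, with log2 ratios from -1.97 to -1.35. The count of lower genes was 95 without the sub-cluster led by F2rl1 and Thbs1, and the counts were 509 and 537 with no floor on level and 83 and 37 at 100 CPM or more.

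**Figure D3:**
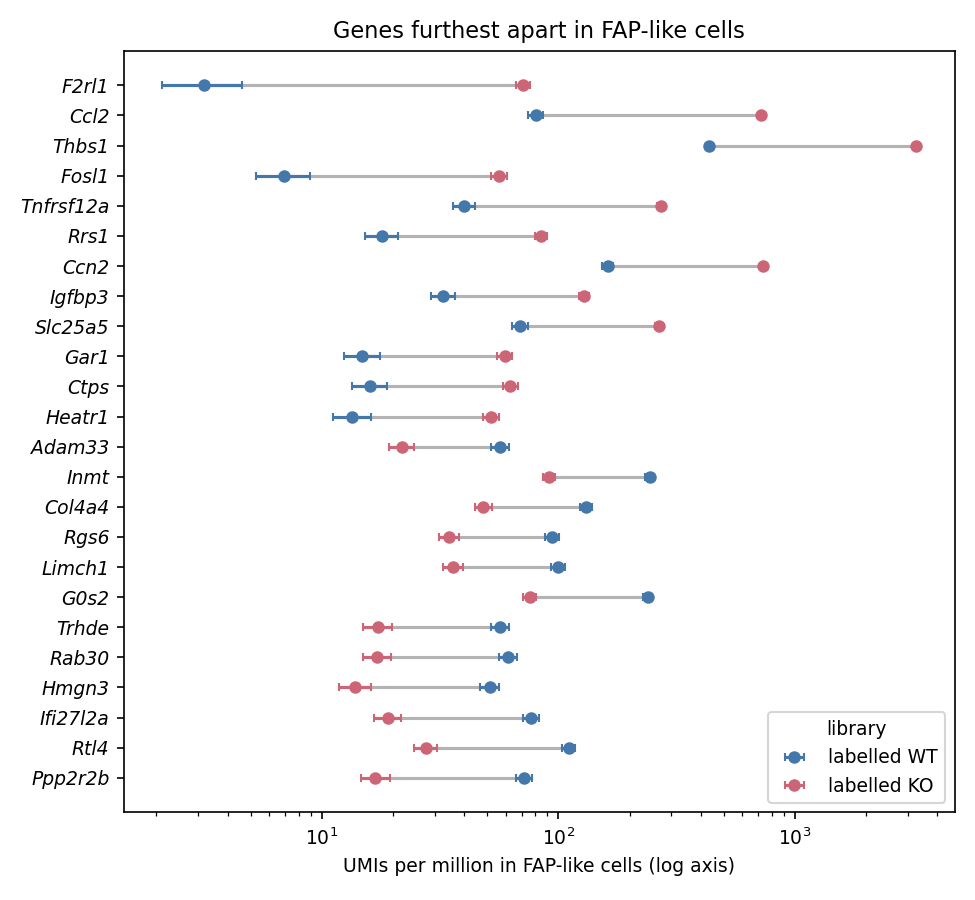
Points give the level of 24 genes in FAP-like cells in CPM on a log axis for the libraries labelled WT and KO, with exact Poisson 95% intervals, and grey lines join the libraries. F2rl1, Ccl2 and Thbs1 lie at 70.8, 718 and 3253 CPM in the library labelled KO, against 3.17, 80.2 and 434 CPM in the library labelled WT.

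Genes of the IGF axis in FAP-like cells lay on both sides. Igfbp3, a carrier of IGF in blood and tissue, was at 32.6 CPM in the library labelled WT and 129 CPM in the library labelled KO, a log2 ratio of 1.95. Igfbp5, another binding protein, was at 1184 and 555 CPM, a log2 ratio of -1.09. Igf1r, the receptor gene, had a log2 ratio of 0.61, the mannose-6-phosphate receptor gene Igf2r -0.67, and Pappa, a protease that frees IGF from its binding proteins, 0.86. Igfbp6 had -0.68, Grb10, an adaptor that dampens receptor signalling, -0.66, Htra1 -0.57, Igf2bp2 0.65, Irs2 0.49, Irs1 -0.26, Igfbp4 -0.24, Insr -0.13 and Igfbp7 -0.04. Of the 17 measured members, 4 were at least 1.5-fold higher and 4 at least 1.5-fold lower, and the median of -0.04 lay at percentile 32.7 of 10000 random matched lists.

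Among the 27 gene lists compared in FAP-like cells, 6 had medians above the central 95% of random lists and 6 below, as a description of these libraries. Genes of the Dpp4/Pi16 state were lower in the library labelled KO, with a median log2 ratio of -0.82 at percentile 0. Of its 20 members, 14 were at least 1.5-fold lower, among them Sema3c at -1.07 and Stmn4 at -1.52. Fibrillar collagen and matrix genes had a median of -0.46 at percentile 0, with 8 of 26 members at least 1.5-fold lower and 1 higher. Col1a1 and Col3a1, the chains of the main fibrillar collagens, had log2 ratios of -1.02 and -1.03, the elastin gene Eln -1.22, and Postn, a matrix protein of repair, 1.21. Interferon response genes had a median of -0.46 at percentile 0.01, with 11 of 29 members lower, such as Ifit1 at -1.21 and Psmb8 at -1.03. That list also lay below the random range in the other classes compared, except T-cell-like (percentile 16.0) and myofibre-like cells (percentile 3.65). Complement genes had a median of -0.45 at percentile 0.485, with C7 at -1.07 and Cd55 at -0.80, and that median was -0.19 at an equal mix of sub-clusters.

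Genes of the unfolded protein and integrated stress responses were higher in FAP-like cells of the library labelled KO, with a median log2 ratio of 0.52 at percentile 100 and 9 of 21 members at least 1.5-fold higher. They included Hspa5, an endoplasmic reticulum chaperone, at 1756 and 3037 CPM, and the amino acid genes Slc7a5 and Asns with log2 ratios of 1.11 and 1.02. This stress response list also lay above the random range in the other classes compared, except macrophage-like (percentile 85.2) and myogenic-like cells (percentile 79.6). Genes of the immune-recruiting state had a median of 0.63 at percentile 100, with 10 of 18 members higher, among them the chemokine Ccl7 at 1.86. The chemokine and cytokine list, which shares Ccl2 and Ccl7 with it, had a median of 0.21 at percentile 98.2. Its members Cxcl13 and Cxcl5 had log2 ratios of 2.86 and 1.56, and 1 cell held 40.7% of the Cxcl13 UMIs of the library labelled KO and another 41.1% of the Cxcl5 UMIs of the library labelled WT. TGF-beta response genes had a median of 0.45 at percentile 99.99, with 8 of 20 members higher, including Timp1 at 13.3 and 39.2 CPM, and with Ccn5 at -2.05. Sterol and lipid synthesis genes had 0.31 at percentile 99.1, with Sqle, an enzyme of cholesterol synthesis, at 1.03. That median came inside the random range at 0.25 with the strict cell filter, and at 0.17 with cells thinned to 2000 UMIs, with members at 50 CPM or more and without the sub-cluster led by F2rl1 and Thbs1. An average with equal weight took the 3 sub-clusters with at least 100 cells per library (216 and 130, 193 and 109, 126 and 103 cells). It left out smaller ones and those led by G0s2 (515 and 78 cells), by Pi16 (234 and 90) and by F2rl1 (14 and 266). Averaged over these 3 sub-clusters, the interferon, sterol and chemokine medians were -0.17, 0.05 and 0.18, inside the random range, and Ifi27l2a, Cxcl13 and Cxcl5 had log2 ratios of 0.13, -0.27 and -0.27. The Dpp4/Pi16 median was then -0.30 and the fibrillar collagen and matrix median -0.28, both still below the range and nearer to 0 than over all FAP-like cells. The TGF-beta median was 0.29 over these sub-clusters, above the range, and 0.18, inside the range, with members at 50 CPM or more, and the chemokine median was 0.11, also inside, without the sub-cluster led by F2rl1 and Thbs1.

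Adipogenic genes had a median of 0.645 at percentile 100, with 9 of 16 members at least 1.5-fold higher. The adipogenic list also lay above the random range in the other classes compared, except macrophage-like (percentile 93.6), perineurial-like (percentile 95.05) and tenocyte-like cells (percentile 72.2). Its members Fabp4 and Cd36 are strongly made by endothelial cells, where Fabp4 was at 6372 and 7744 CPM. Fabp4 was at 90.3 and 229 CPM in FAP-like cells and at 81.1 and 428 CPM in T-cell-like cells, where 1 cell held 63.3% of its UMIs in the library labelled WT. A FAP-like sub-cluster of 27 and 54 cells was led by Fabp4, Cd36 and other endothelial genes, so free RNA and remaining doublets are not separated from FAP-like expression here. The adipogenic median was 0.39 averaged over 3 sub-clusters and 0.26 at an equal mix of 8. Zfp423, a regulator of the preadipocyte state, was lower, with a log2 ratio of -1.27. Nuclear genes of oxidative phosphorylation had a median of -0.24 at percentile 0.06, with Ndufa13 at -0.84 and Cycs, the cytochrome c gene, at 1.15. Genes of the Col15a1/Cxcl14 state had a median of -0.19 at percentile 2.36, near the edge of the range. It came inside at -0.12 with TMM factors, at -0.16 with each library clustered alone, at -0.12 averaged over sub-clusters and with members at 50 CPM or more. The other 15 lists lay inside the random range, among them FoxO targets at -0.13, dissociation stress at 0.17, cell cycle at 0.18 and autophagy and lysosome at -0.17. Dissociation stress lay above it, at 0.28, with each library clustered alone and, at 0.22, without the sub-cluster led by F2rl1 and Thbs1. Autophagy and lysosome lay below it, at -0.18, in cells with a Pdgfra UMI and, at -0.20, with members at 50 CPM or more. From those lists, the secreted factors Angpt1, Wnt5a and Hgf had log2 ratios of -1.29, -1.10 and -1.07, with 33.7% of the Hgf UMIs of the library labelled WT in 1 cell, and Timp3, an inhibitor of metalloproteases, had 1.58.

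**Figure D4:**
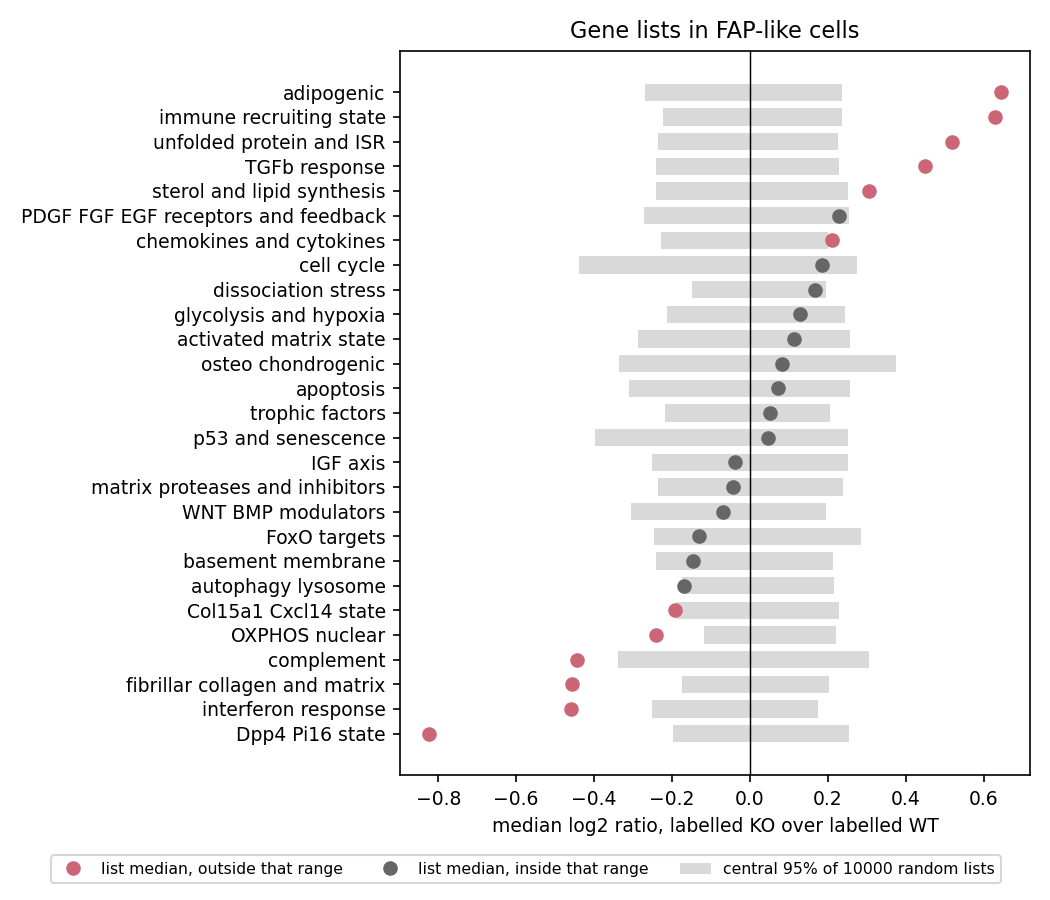
Median log2 ratio of CPM, library labelled KO over library labelled WT, in FAP-like cells for 27 gene lists, as points, with grey bars for the central 95% of 10000 random matched lists. Points outside that range are red. The Dpp4/Pi16 state lies lowest at -0.82, and the immune-recruiting state and stress response lists lie above their bars at 0.63 and 0.52.

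The mix of states within FAP-like cells was compared with clusters made without the 456 genes that were at least 2-fold apart. A Col15a1/Cxcl14-like group led by Fbln7, G0s2 and Mme held 33.9% of FAP-like cells in the library labelled WT (523 cells; 31.6 to 36.3%) and 7.89% in the library labelled KO (84 cells; 6.35 to 9.68%). Another Col15a1/Cxcl14-like group, led by Dlk1, held 4.93 and 5.83%. A Dpp4/Pi16-like group led by Pi16 and Cmah numbered 232 cells in the library labelled WT (13.3 to 16.9% of FAP-like cells) and 88 in the library labelled KO (6.69 to 10.1%), and a smaller Dpp4/Pi16-like group numbered 14 and 6 cells. A group led by F2rl1 and Thbs1 was 0.13% (2 cells) and 23.5% (250 cells), so it lies almost wholly in 1 library and may stand for that library, not for a cell state. The group led by Fbln7 and that led by F2rl1 together held 34.0 and 31.4% of FAP-like cells. Among sub-clusters made with all genes, 8 had at least 30 cells per library. Pdgfra was lower in the library labelled KO in all 8, with log2 ratios from -1.08 to -0.68, whereas Igf1 was lower in 4 of these 8, with log2 ratios from -0.78 to 1.09.

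The genes set apart in FAP-like cells were then followed in the other cell classes. Each class was read over the genes with at least 20 CPM there in 1 library, so the genes differ between classes. The 283 genes at least 2-fold higher had a median log2 ratio of 1.25 in FAP-like cells, 0.98 in tenocyte-like cells (242 measured), 0.90 in myogenic-like cells (231) and 0.87 in perineurial-like cells (221). Their median was lower in mural-like cells at 0.35 (198), endothelial-like cells at 0.29 (176), macrophage-like cells at 0.24 (187), glial-like cells at 0.23 (179), T-cell-like cells at 0.19 (196) and myofibre-like cells at 0.14 (122). Of the 173 genes at least 2-fold lower, those measured had medians of -0.98 in tenocyte-like cells (91), -0.95 in myogenic-like cells (55), -0.65 in endothelial-like cells (59) and -0.30 in glial-like cells (80). Of the measured members of the higher set, 95.5% were higher in tenocyte-like cells and 64.8% in myofibre-like cells.

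**Figure D5:**
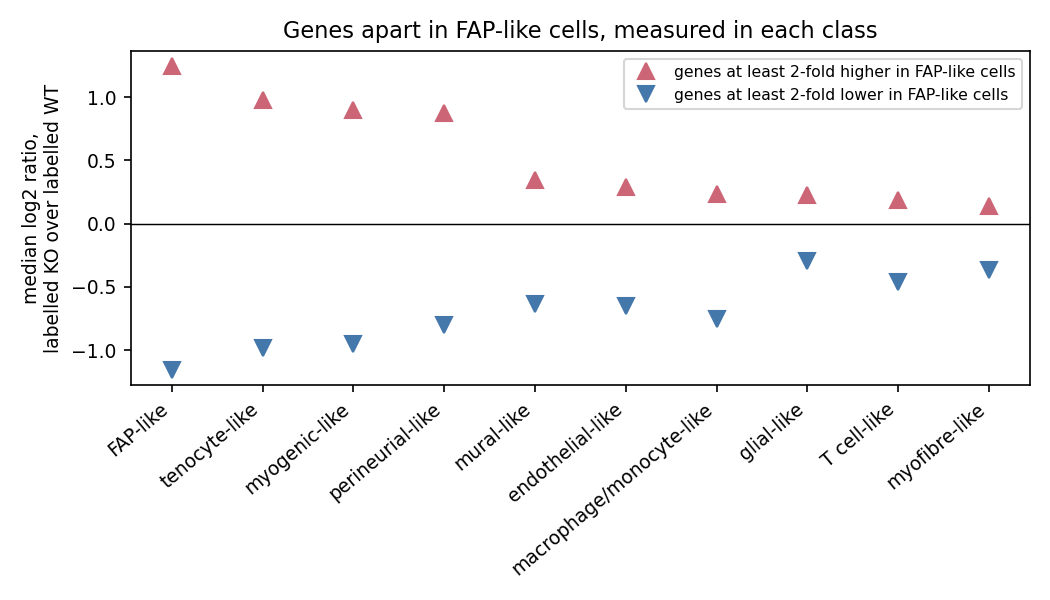
Median log2 ratio of CPM, library labelled KO over library labelled WT, by cell class for the genes at least 2-fold higher and at least 2-fold lower in FAP-like cells. Each median covers the genes of the set with at least 20 CPM in 1 library in that class. Tenocyte-like cells lie nearest to FAP-like cells, at 0.98 for the higher and -0.98 for the lower genes, and myofibre-like cells lie at 0.14 for the higher genes.

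In tenocyte-like cells, 210 of 6989 genes were at least 2-fold higher and 197 at least 2-fold lower in the library labelled KO. Sfrp4 and Sfrp2, secreted modulators of WNT signalling, had log2 ratios of -3.17 and -2.83, with 28 of the 37 Sfrp4 UMIs of the library labelled KO in 1 cell, and Igfbp5 was at 592 and 108 CPM. Rrs1, Gar1 and Slc25a5 were higher here too, with 2.23, 1.88 and 1.80. Perineurial-like cells had Tnfrsf12a at 3.15 and the stress response list at a median of 1.03 (percentile 100), with 14 of 18 members at least 1.5-fold higher.

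Myogenic-like cells had 203 of 6393 genes at least 2-fold higher and 156 at least 2-fold lower. Genes of quiescent satellite cells, the resting muscle stem cells, had a median log2 ratio of -0.45 at percentile 0, and genes of activated or differentiating cells had -0.21 at percentile 9.34, inside the random range. They included Calcr, a receptor that holds satellite cells at rest, at 340 and 150 CPM, and Fgfr4, Hes1 and Notch3 with log2 ratios of -1.20, -0.95 and -0.79. Fosl1 and Heatr1 were higher, with 1.84 and 1.97, as was the cytokine-induced gene Cish with 2.23, and the sterol and lipid synthesis list had a median of 0.70 at percentile 100.

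Endothelial-like cells had 17 of 6630 genes at least 2-fold higher and 90 at least 2-fold lower. Lpl, the lipase that acts on vessel walls, was at 710 and 1741 CPM, while H2-Q7, a class I histocompatibility gene, and Apobec3, an antiviral gene, had log2 ratios of -1.77 and -1.82. Capillary genes had a median of 0.38 at percentile 99.98, with Rgcc at 0.92 and Car4 at 0.85, and arterial genes a median of -0.38 at percentile 0.03, with Alpl at -1.14 and Bmx at -1.10. The endothelial mix also differed, as a cluster led by Cytl1, Sema3g and Bmx held 1000 of 3386 endothelial-like cells in the library labelled WT and 1277 of 7109 in the library labelled KO. Interferon response genes had a median of -0.78 at percentile 0, with 22 of 31 members at least 1.5-fold lower. An endothelial-like cluster led by Slc1a1 and the interferon response genes Rsad2 and Iigp1 held 399 cells in the library labelled WT and 1360 in the library labelled KO, a larger part of the latter.

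Macrophage-like cells were the same pair of clusters in different proportions in each library, so their gene levels compare different mixes. A cluster led by Mrc1 and C1qa held 275 cells of the library labelled WT and 158 of the library labelled KO, and a cluster led by Plac8, Chil3 and Ccr2 held 77 and 172. Genes of resident macrophages had a median log2 ratio of -0.92 at percentile 0, with Folr2 at -1.70 and Cbr2 at -1.39. Vcan, a matrix proteoglycan gene made by monocytes, was at 36.3 and 799 CPM, and Chil3, a chitinase-like gene, at 30.1 and 461 CPM. In the library labelled WT, 1 cell held 30.3% of the Vcan UMIs and 1 cell held 38.1% of the Chil3 UMIs. Cell cycle genes had a median of -1.54, with Top2a at -3.47.

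Glial-like cells had Itih5 at 353 and 1411 CPM, and Cntf, a neurotrophic factor of Schwann cells, with a log2 ratio of -1.73. Mural-like cells had Ccl2 at 43.4 and 161 CPM and Postn with -1.40. Ccl2 was at 300 CPM in the low-UMI barcodes of the library labelled KO, so free RNA is not separated from mural-like expression of it. Myofibre-like cells had the heavy chain gene Myh1 with -1.55, the stress-induced gene Ddit4 with 2.34 and dissociation stress genes at a median of 0.83 (percentile 100). Of the Myh1 UMIs of the library labelled KO, 1 cell held 32.2%. In T-cell-like cells the chemokine gene Ccl5 was at 3057 and 904 CPM.

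A last comparison looked for genes set apart in every class, which can come from strain background, library preparation or free RNA as well as from the genotype. Of 2881 genes past the floors in all 10 classes, none was at least 2-fold higher in each and 1 was at least 2-fold lower in each. That gene was Gm8797 (ENSMUSG00000103034), with a mean log2 ratio of -2.35 and a range of -2.67 to -1.89. Nuclear genes of oxidative phosphorylation had medians below the random range in all 10 classes, from -0.42 in mural-like cells to -0.19 in tenocyte-like cells. Ribosomal protein genes had medians from -0.30 to -0.12 in 9 of the 10 classes and 0.02 in perineurial-like cells, and the mitochondrial share of UMIs was lower in the library labelled KO in all 10, such as 1.33 and 1.07% in FAP-like cells. More cells of the library labelled KO carried a UMI of Hbb-bs, a haemoglobin gene, with 2.30 and 20.8% of endothelial-like cells, 0.65 and 23.3% of tenocyte-like cells and 1.82 and 22.4% of FAP-like cells. Its level in FAP-like cells ran the other way, at 172 and 46.6 CPM.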

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

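All weighing tests in this part were chosen after the results they address had been seen.

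In FAP-like cells of the library labelled KO Igf1 was not lower, while its log2 ratio was -1.61 in tenocyte-like cells, -1.98 in macrophage-like cells (whose mix of clusters differs between the libraries), -1.41 in endothelial-like cells and -1.01 in mural-like cells, directions opposite to that in FAP-like cells. The endothelial-like levels were only 13.7 and 4.55 CPM, and the mural-like levels rest on 19 and 18 UMIs. Free RNA and remaining doublets are not separated from expression in these classes. FAP-like and tenocyte-like cells, which held the most Igf1 UMIs, were a smaller share of the library labelled KO. Free Igf1 RNA may therefore have been lower in that library. For FAP-like cells, free RNA as the whole source of Igf1 is argued against by its level in the low-UMI barcodes of the library labelled KO, where Igf1 CPM was 17.6% of that in FAP-like cells. This takes those barcodes to hold mainly free RNA, which was not tested. A mix of states that hides a lower average is argued against by the log2 ratio at an equal mix of 8 sub-clusters, -0.0056. That mix leaves out the sub-cluster led by F2rl1 and Thbs1, with 14 and 266 cells. Igf1 was lower in 4 of the 8, with log2 ratios from -0.78 to 1.09. The sub-cluster led by G0s2 had -0.43 (-0.63 to -0.23) and that led by Pi16 had 1.09 (0.83 to 1.37). A lower level in particular sub-clusters stays open, since the average cannot show it. Tags outside a removed part of the gene and a removal in few FAP-like cells stay open, as does the genotype itself, and the difference between classes was not tested.

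FAP-like cells were a smaller share of the library labelled KO. The low-UMI barcodes in the denominator are argued against as the whole cause, since without them the share was 7.10%, below the interval of the library labelled WT. A lower recovery of several stromal classes together may account for it, since the share ratios of tenocyte-like and perineurial-like cells were at most 1.25 times that of FAP-like cells, though without the low-UMI barcodes B-cell-like, macrophage-like, T-cell-like and myogenic-like cells also had share ratios below 1, at 0.497, 0.637, 0.71 and 0.818. Shares sum to a whole, so more endothelial-like cells lower the others, but that alone would lower them alike. The ratios were instead 0.469 for FAP-like, 0.95 for mural-like, 1.052 for glial-like, 1.056 for myofibre-like and 2.77 for neutrophil-like cells. Fewer FAP-like cells in the muscle of that strain stays open as untested.

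The 283 genes at least 2-fold higher in FAP-like cells, led by F2rl1, Ccl2 and Thbs1, had a median log2 ratio of 1.25. A different mix of FAP-like states is argued against as the whole cause, since their median was 0.86 at an equal mix of sub-clusters. For a response shared by all classes, their median over the other classes was 0.29, just under the bound set against it at 0.25 of the value in FAP-like cells, but class medians ran from 0.14 in myofibre-like cells to 0.98 in tenocyte-like cells. Read by that spread, a reading chosen after the value was seen, a shared response, a genotype effect and a difference in handling cannot be told apart for these genes.

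A cluster of 2863 low-UMI barcodes was found in the library labelled KO and not in the library labelled WT. Its profile had a Pearson correlation of 0.961 across genes with the summed other cells of its library, where other clusters reached at most 0.591, and genes are not independent replicates. Fibrillar collagen and matrix genes, lower in FAP-like cells, had medians of 1.10 in T-cell-like and 0.98 in macrophage-like cells, where 1 cell held 88.0% and 62.4% of the Dcn UMIs of the library labelled KO. That list was below the random range, as in FAP-like cells, in tenocyte-like (-0.53), endothelial-like (-0.61), glial-like (-0.43) and mural-like cells (-0.20). It lay inside the range in myofibre-like, myogenic-like and perineurial-like cells. In glial-like cells sterol and lipid synthesis genes had a median of -0.36 and TGF-beta response genes -0.20, opposite to FAP-like cells. These differences between classes were not tested.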

How the results depend on the processing

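The alternatives that left out the cluster found in 1 library, the genes at least 2-fold apart, the Apod and Grm8 clusters, the endothelial and myofibre sub-clusters, or the F2rl1 and Thbs1 sub-cluster were added after the data were seen. No paired analysis was possible because there is 1 library per group. Of the main results under the alternatives, 87 stayed within their bounds and 20 moved. Of gene list medians 428 stayed on their side of the random range and 29 crossed its edge, and none that lay outside it changed sign, though medians inside it did, such as FoxO targets at 0.07 in thinned cells. Lists and named genes were likewise counted once per setting, and of the named gene results 1579 stayed, 401 moved and 4 reversed. The FAP-like share ran from 12.5 to 18.6% in the library labelled WT and from 5.74 to 7.11% in the library labelled KO, lower in the latter in all 8 settings that give it. The Igf1 log2 ratio ran from 0.04 to 0.51 over 15 settings. The highest came with each library clustered alone, where fewer cells of the library labelled WT were FAP-like.

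With the loose filter 11246 and 18747 barcodes passed and the share in the library labelled WT was 13.9%. With the strict filter 7655 and 14354 passed and the shares were 18.6 and 7.11%. With doublets kept 10272 and 18554 passed. Those counts follow from the filters. Clustered alone, the library labelled WT had 12.5% and Igf1 a log2 ratio of 0.51. Without the cluster found in 1 library the share in the library labelled KO was 7.10%. Igf1 was at 0.17 with TMM factors and at 0.35 averaged over 3 sub-clusters, which leave out those led by G0s2, by Pi16 and by F2rl1. With no low-value filter 509 genes were higher and 537 lower, and at 100 CPM or more 83 and 37, as more or fewer genes enter. With a pseudocount of 5 CPM 110 were lower, and without the F2rl1 and Thbs1 sub-cluster 95. Averaged over sub-clusters, Ifi27l2a had 0.13, Cxcl13 -0.27, Cxcl5 -0.27 and Dkk3 -0.67, all reversed, and the interferon, sterol, chemokine and Col15a1/Cxcl14 lists, at -0.17, 0.05, 0.18 and -0.12, came inside the random range, while the p53 and senescence list, at 0.34, left it. At least 1 other setting moved the sterol, chemokine, TGF-beta and Col15a1/Cxcl14 lists inside the range, and the dissociation stress, autophagy, growth factor receptor, activated matrix and basement membrane lists outside it. Except where stated, the cause was not tested. Depth limits genes near the floors, and the median ratio of genes at 50 CPM or more was 0.05.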

Other observations

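Further members of the fixed lists stood apart in FAP-like cells. Cdkn1a, an inhibitor of the cell cycle, was at 286 CPM in the library labelled WT and 543 CPM in the library labelled KO, and the p53 targets Aen and Eda2r had log2 ratios of 1.58 and 1.29, while the p53 and senescence list had a median of 0.05 at percentile 77.1, inside the random range. Pcna, a replication clamp gene, had 0.96, while the cell cycle list as a whole lay inside the random range. Gas1, a growth arrest gene, had -1.22, and the WNT effector gene Lef1 and the BMP target Id1 had 1.12 and 1.13. Slc2a1, the glucose transporter of many cells, had 1.19.

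In tenocyte-like cells WNT and BMP modulators had a median log2 ratio of -0.54 at percentile 0, with 10 of 22 members at least 1.5-fold lower, and complement genes -0.88 at percentile 0. Perineurial-like cells had interferon response genes at a median of -1.004 with 19 of 28 members lower. Dissociation stress genes had medians above the random range in tenocyte-like cells at 0.39, mural-like cells at 0.44 and endothelial-like cells at 0.29, and below it in macrophage-like cells at -0.12.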
